A study of Caenorhabditis elegans with 2 samples.

How the data were processed

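ELT-3 binding was measured by ChIP-seq in whole L1 larvae, and the 2 biological replicates of the single group were taken from the submitters' labels. Per the labels, chromatin was sheared by sonication, the antibody field names elt-3, and the protein carried a GFP-FLAG tag. A control experiment is named in the labels and is not analysed here.

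The deposited files were region lists in narrowPeak format. Each listed region carries a signal value and a value in the q column, both treated as a score whose scale the authors do not state in the sources used here. The q column went from -0.119 to 2.17 in the pooled list, so it was not read as a log-scaled q-value, and it was not used in any test. Per the deposited notes on the files, the replicate lists came from the alignments of 1 replicate and a control file, the pooled list from the alignments of both replicates and a control file, and the optimal set from the pooled and replicate lists. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here. The longer lists hold background as well as peaks, per their titles in the deposited notes. Regions were 260 bp wide in replicate 1 and 250 bp in the other lists. In ce11 the optimal set equalled the 253 pooled regions of largest signal (0.843% of the pooled list), and in ce10 the 255 of largest signal, so the optimal set was in effect a threshold on pooled signal. Read depth is not given in the sources used here, and precision was therefore expressed through numbers of peaks. Intervals are 95% exact (Clopper-Pearson) binomial intervals and cover counting error only. With 2 replicates of 1 group, p-values over peaks describe these libraries.

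Positions are in ce11, 1-based, and were set against the WBcel235 genome, which is the same assembly, with the Ensembl release 115 annotation of 19973 protein-coding genes. Lists in ce10 were used for overlaps and correlations between lists alone, and no coordinates were converted. The summit is the position the files give in each region. A promoter reached from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene. A peak was assigned to the gene with the nearest 5′ end if that lay within 2000 bp. Summits matched between lists when within 100 bp.

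Random expectation for promoter and tRNA shares (within 200 bp of a tRNA gene) came from 100000 random placements on the same chromosome, and for overlaps from 100000 shifts along the chromosome. Correlations and differences of medians were tested with 100000 permutations, and 1e-05 is the smallest p these can give. Shares of WGATAR within 50 bp of the summit, on either strand, were compared with windows centred 500 bp to each side by Fisher's exact test. Every 6-base word joined with its reverse complement was tested in the same way. Windows were treated as independent, so the pairing of a summit with its flanks was not used. A flank could also fall on another peak. All tests were 2-sided, except the upper-tailed test of overlaps, with a threshold of 0.05. Gene lists were tested by Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over 22 lists, and words of 6 bases over all words. Region density at elt-3 and unc-119 was counted within 20 kb of the middle of the gene and ranked among 40 kb windows placed every 1000 bp. For elt-3 the count was repeated, after the data were seen, with the gene left out and a middle part of the same length left out of each window.

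The tests, gene lists, alternatives and naming rule were fixed before the data were examined. The lists were cuticle collagens, epidermal regulators, GATA factors, molting and non-collagen cuticle genes, hedgehog-related and patched-related genes, epidermal antimicrobial peptides, osmotic response, epidermal junction and attachment, tyrosine catabolism, glutathione transferases, cytochrome P450, UDP-glucuronosyltransferases, nuclear receptors, markers of intestine, body muscle, pharynx, neurons and germline, ribosomal proteins, heat shock proteins and histones. Named genes were those assigned to the 15 peaks of largest signal, up to 4 bound members of each list by signal, elt-3 and unc-119, every epidermal regulator and GATA factor, and the 5 words of 6 bases with the smallest p. Genes outside this rule are said to be so chosen where a value singles them out, or stand in counts of list members.

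Alternatives fixed in advance were the peaks of larger signal, each replicate's strongest regions in place of the optimal set, removal of peaks near elt-3 and unc-119, other promoter, motif and assignment distances, another GATA word, other control windows, another gene background, other matching rules and the ce10 lists. Splits by promoter or by GATA site, ends of transcripts, and correlation over all pooled regions were added after the data were seen.

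The tests of words and gene lists were checked on simulated data. With a planted word in 0%, 20% and 30% of windows, the numbers of words called were 0, 1 and 2, the planted word among them when there was one. With no planted genes, 2 lists were called over 100 draws in all, and 5, 10 and 15 planted collagen genes were called in 72, 100 and 100 of 100 draws. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.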

Results

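ELT-3 is a GATA-type zinc finger transcription factor of the C. elegans epidermis. Its binding was mapped by ChIP-seq in whole L1 larvae of mixed sex from strain OP75, an unc-119 mutant line with a transgene for ELT-3 tagged at its C terminus with GFP and FLAG. The data form 1 group of 2 biological replicates, and no second condition or stage was compared. The authors' region lists held 30000 regions for replicate 1, 15646 for replicate 2 and 30000 for the replicates pooled, in the genome build ce11. The authors' optimal set of 253 peaks, each 250 bp wide, is titled as thresholded by reproducibility between ranked lists (IDR). These 253 were the pooled regions with the largest signal values, from 42.6 to 174. Whether each peak passed that threshold on its own is not stated in the sources used here. The signal value is the authors' own score per region and its scale is not given in the sources used here, nor are the read depths. The members of the optimal set are called peaks and those of the longer lists regions.

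The 5 strongest ELT-3 peaks lay upstream of rpl-3, iff-2, rpl-15, cdc-48.1 and rpl-35, and the next within elt-3 itself. The largest signal value, 174, stood on chromosome III from 3867464 to 3867713, between genes and 265 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. It was followed by iff-2 (signal 167, 68 bp upstream), a homologue of the translation factor eIF5A, by rpl-15 (149, 359 bp upstream), by cdc-48.1 (148, 164 bp upstream), which encodes the AAA ATPase known as p97 in mammals, and by rpl-35 (146, 465 bp upstream). The sixth, at 140.2, lay on chromosome X from 13937436 to 13937685 in an intron of elt-3, 2687 bp downstream of its 5′ end. Further down the first 15 peaks came mstr-1 (111), the kinetochore gene ska-3 (109), R11A5.6 (99.3), rpl-11.2 (88.1) and tasp-1 (87.1). The R11A5.6 summit lay within an intron of the phosphoenolpyruvate carboxykinase gene pck-2. Each name is that of the gene with the nearest 5′ end, and other genes can lie within 2000 bp of the same summit. Another 4 of the 15 lay more than 2000 bp from the 5′ end of any protein-coding gene, the strongest of them on chromosome IV from 13919269 to 13919518 with a signal of 132.

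Both replicates placed these peaks at the top. The rpl-3 peak ranked 3 in replicate 1 and 1 in replicate 2, cdc-48.1 ranked 1 and 4, iff-2 ranked 2 and 3, and the elt-3 intron ranked 6 in each. Of the 25 strongest peaks, 24 were among the 253 strongest regions of both replicates. Over all 253 peaks, 251 (99.2%, 95% exact binomial interval 97.2 to 99.9) had a region of replicate 1 with its summit within 100 bp, and 248 (98.0%, 95.4 to 99.4) had such a region of replicate 2. Among the 253 strongest regions of each replicate the shares were 61.7% (55.4 to 67.7) and 68.8% (62.7 to 74.4), and 93 of the strongest regions of replicate 1 (36.8%) matched a strongest region of replicate 2. Shifted positions gave on average 15.5 and 8.20 matches to the full lists, and averages no higher than 0.138 for the strongest regions (upper-tailed permutation p = 1e-05 for each, the smallest possible). The optimal set was made from these replicates, so the overlap is not independent evidence.

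Across the whole optimal set, from rpl-3 down, the order of the peaks by signal differed between the replicates. Over the 246 peaks matched in both, Spearman's rho was -0.0038 (permutation p = 0.953) and Pearson's r of the log2 values was 0.22 (permutation p = 0.00043). The replicates lay a median of 1.33-fold apart, and 30 peaks (12.2%) differed 2-fold or more. Over 4508 pooled regions matched in both, a set chosen after the data were seen, rho was 0.289 (permutation p = 1e-05, the smallest possible). Peaks are not independent replicates, and the choice of peaks by their pooled signal narrows the range over which they can correlate. Under that choice a peak low in 1 replicate tends to enter only if it is high in the other. The choice itself thus lowers the correlation, and the value over the optimal set does not measure agreement between the libraries as a whole.

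**Figure D1:**
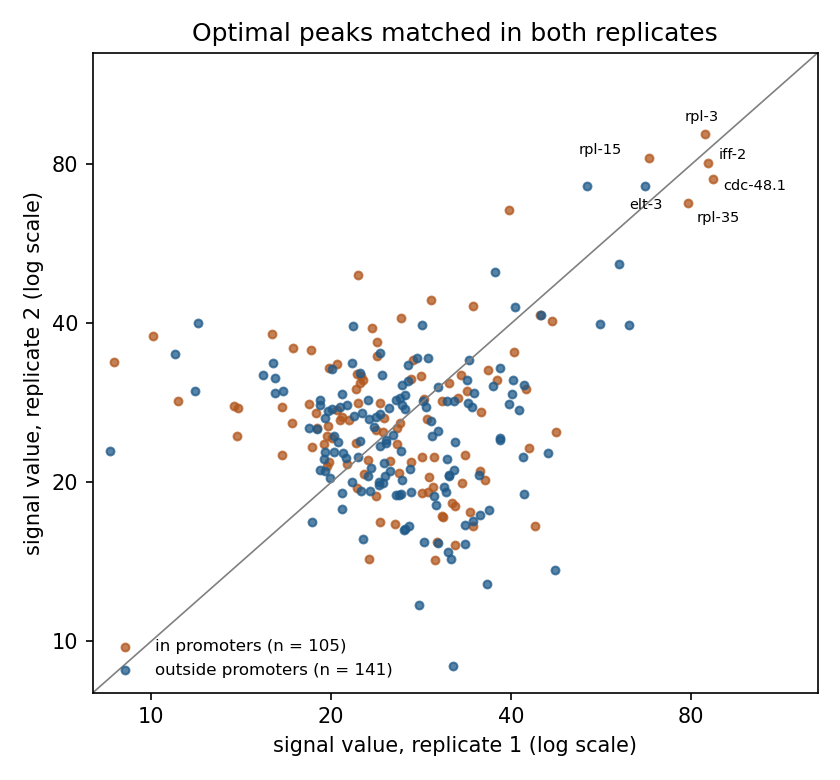
Signal value of each of 246 optimal peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log scales in the authors' units, coloured by place; the line marks equal values. The rpl-3, iff-2, rpl-15, cdc-48.1, rpl-35 and elt-3 peaks stand apart at the upper right, while the other peaks form a cloud with little order between replicates.

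ELT-3 peaks were concentrated near the 5′ ends of genes. Of 253 summits, 106 (41.9%, 95% exact binomial interval 35.7 to 48.2) lay from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene, against 20.8% of summits placed at random on the same chromosome (2-sided permutation p = 1e-05, the smallest possible). Of the 147 peaks outside these promoters, 81 lay between genes, 59 in introns and 7 in exons. Within 2000 bp, 159 peaks were assigned to 152 nearest genes of 19973, and the other 94 lay farther away. The promoter share was 33.99% in the strongest regions of replicate 1 and 45.5% in those of replicate 2, above random placement in both (permutation p = 1e-05).

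Ribosomal protein genes stood out among the bound genes. Of 80 such genes, 13 (16.2%) were assigned a peak within 2000 bp, against 0.703% of other genes (odds ratio 27.4, 2-sided Fisher's exact p = 3.71e-14, adjusted p = 8.17e-13 by Benjamini-Hochberg over 22 lists). The 4 strongest were rpl-3, rpl-15, rpl-35 and rpl-11.2, and all 13 summits lay in promoters. The list passed in the strongest regions of each replicate alone, with 9 genes in replicate 1 (Fisher's exact test, adjusted p = 9.13e-08) and 12 in replicate 2 (adjusted p = 5.07e-11). It did not pass after adjustment among the 112 peaks that held a GATA site, a smaller set. There 2 of 80 genes remained, 2.5% against 0.288% of other genes (odds ratio 8.87, Fisher's exact p = 0.0236, adjusted p = 0.267).

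Genes of the epidermis and cuticle were bound in small numbers. Of 174 cuticle collagen genes, whose products form the exoskeleton, 4 were assigned a peak (odds ratio 3.11, Fisher's exact p = 0.0449, adjusted p = 0.334), namely col-166 (signal 49.0), col-167 (48.9), col-103 (45.5) and col-94 (44.3). Among the epidermal antimicrobial peptide genes 1 of 21 was bound, nlp-31 (54.2, in its UTR), and among genes of epidermal junctions and attachment 1 of 19, mup-4 (55.2, in its intron). Nuclear receptor genes counted 4 of 269, with nhr-14 (56.0), nhr-21 (49.3), nhr-80 (48.8) and nhr-57 (48.08), and cytochrome P450 genes 2 of 74, cyp-29A4 (56.0) and cyp-34A1 (46.3). Histone genes counted 2 of 50, his-37 (60.9) and the linker histone gene his-24 (43.8), and heat shock protein genes 1 of 20, hsp-1 (46.7). None of these lists passed Fisher's exact test, with adjusted p = 0.334 for each.

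No gene of the remaining 12 lists was assigned a peak within 2000 bp. These were the genes of molting and the non-collagen cuticle (52), hedgehog-related (59) and patched-related genes (26), genes of the osmotic response (10) and of tyrosine catabolism (6), glutathione transferases (44), UDP-glucuronosyltransferases (67), and markers of intestine (20), body muscle (19), pharynx (14), neurons (26) and germline (22). Across all protein-coding genes 0.761% were assigned a peak, so an empty list of this size shows no depletion. The limit of 2000 bp also left out 94 peaks. Some of those were nearest to members of these lists, among them tatn-1 (3860 bp), ptc-3 (5190 bp) and the neuron marker snt-1 (11514 bp), named after their values were seen. In tests on simulated sets of bound genes, 5 planted genes of the 174 collagens were called in 72 of 100 draws and 10 in 100 of 100, so smaller groups could have been missed. When every gene within 2000 bp of a summit was counted, 25 of 80 ribosomal protein genes were bound and 3 lists passed Fisher's exact test, the others being antimicrobial peptides (nlp-30, nlp-31 and nlp-34, 3 of 21, adjusted p = 0.0222) and histones (4 of 50, adjusted p = 0.0234). The 3 peptide genes shared 1 peak and the 4 histone genes 2 peaks, so neighbouring genes were counted as separate cases that are not independent, and these 2 calls rest on that counting.

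Of 23 regulators of epidermal fate or of the GATA family, elt-3 was the gene assigned a peak (signal 46.6, 1797 bp downstream of its 5′ end, in an intron). The molting regulator nhr-23 held a peak in an intron 2708 bp from its 5′ end (signal 58.1), beyond the distance set for assignment, with a signal of 47.4 (rank 13) in replicate 1 and of 13.6 (rank 2237) in replicate 2. No peak was nearest to elt-1, elt-2, elt-4, elt-6, elt-7, egl-18, end-1, end-3, med-1, med-2, lin-26, nhr-25, blmp-1, rnt-1, bro-1, ceh-16, lin-29, lin-22, grh-1, nhr-73 or nhr-74. Below the optimal set, the strongest pooled region within 2000 bp ranked 508 for blmp-1 (signal 34.6) and 979 for nhr-25 (29.7). The list of epidermal regulators (1 of 16, odds ratio 8.70, adjusted p = 0.334) and that of GATA factors (1 of 11, odds ratio 13.05, adjusted p = 0.334) did not pass Fisher's exact test.

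The GATA site WGATAR (W is A or T, R is A or G) was more frequent at the summits than beside them. It lay within 50 bp of 112 of 253 summits (44.3%, 95% exact binomial interval 38.0 to 50.6), against 23.5% of 506 windows centred 500 bp to either side (odds ratio 2.58, 2-sided Fisher's exact p = 9.79e-09). At the other 29747 pooled regions the share was 21.4%. Within the optimal set GATA sites were mostly at peaks away from promoters, in a split chosen after the data were seen: 83 of 147 such peaks held one (56.5%, 48.0 to 64.6; flanks 24.5%, Fisher's exact p = 6.32e-11), against 29 of 106 promoter peaks (27.4%, 19.1 to 36.9; flanks 22.2%, p = 0.330). The shares differed between the places (odds ratio 3.44, Fisher's exact p = 6.08e-06). In the strongest regions of replicate 1 taken alone the difference did not pass (44.9% against 32.6%, p = 0.0604), and in those of replicate 2 it did (60.1% against 28.7%, Fisher's exact p = 6.57e-07). It was not detectable in the pooled regions ranked 254 to 1000, which took no part in finding it (40.1% against 36.9%, Fisher's exact p = 0.423), and was reversed over all other pooled regions (20.9% against 23.03%, Fisher's exact p = 0.000184).

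**Figure D2:**
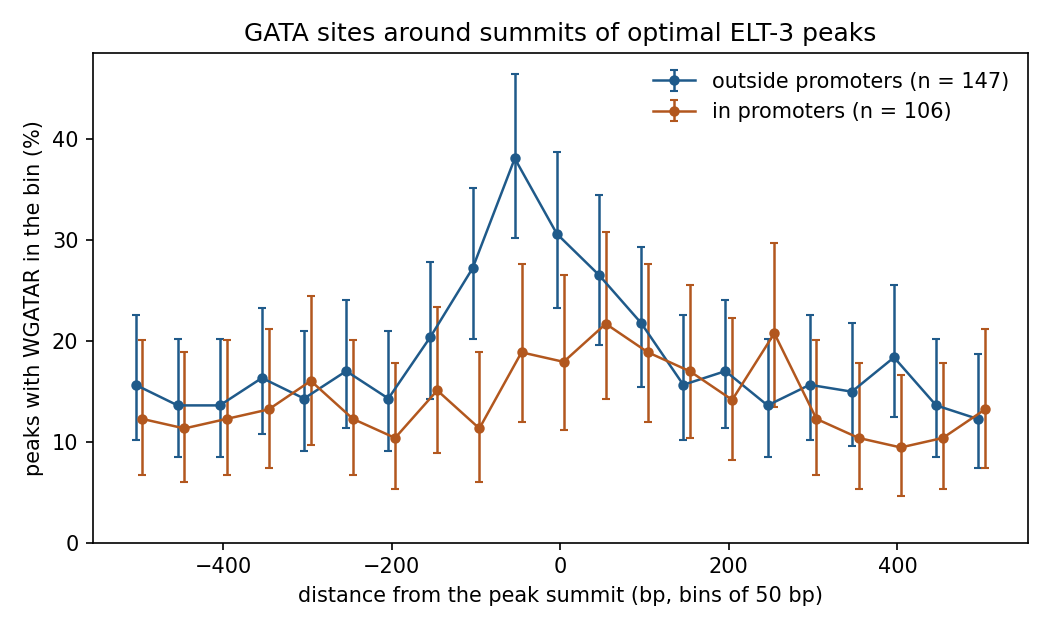
Share of optimal peaks with WGATAR in each 50 bp bin (y axis, percent) by distance of the bin from the summit (x axis, bp), for 147 peaks outside promoters and 106 in promoters; bars are 95% exact binomial intervals. In the bin at the summit the share was 30.6% outside promoters and 17.9% in promoters, and outside promoters it was highest, at 38.1%, in the bin 50 bp to the left.

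The contrast ran through the first 15 peaks. All 7 of those outside promoters, including the elt-3 intron with 3 sites, held WGATAR, and none of the 8 in promoters did, among them rpl-3, iff-2, rpl-15, cdc-48.1 and rpl-35. These few peaks were singled out after their values were seen. Of the 13 peaks nearest to a ribosomal protein gene, those of rpl-24.1 and rpl-7A held a site (15.4%), against 45.8% of the other peaks and 29.03% of the other promoter peaks. The other peaks include some within 2000 bp of a ribosomal protein gene but nearer to another gene.

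Words of 6 bases at the summits included the GATA core. Of all such words, 176 were more frequent within 50 bp of the summits than in the flanks and 113 less frequent (Fisher's exact test, adjusted p under 0.05 by Benjamini-Hochberg). The 5 words with the smallest p were AAAATT (8.30% against 38.1%), TAAAAA (5.93% against 32.8%), TTAAAA (4.74% against 27.5%) and AAAAAT (16.6% against 44.9%), all less frequent at summits, and GATAAG (24.9% against 5.73%, Fisher's exact p = 2.62e-13, adjusted p = 1.09e-10), which was more frequent. Summit windows held 45.4% ± 7.7 G and C bases (SD, n = 253) and flanks 35.8% ± 6.9, and the tests of words did not correct for this. Such a difference favours words of G and C at summits over words of A and T. Words were not tested as a class. Outside promoters GATAAG stood at 30.6% against 5.78% in the flanks, and in promoters the word CGCTCC stood at 16.98% against 0% (Fisher's exact test, adjusted p = 6.33e-07), a word named after its values were seen.

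Chromosome X held 70 of 253 peaks (27.7%, 95% exact binomial interval 22.2 to 33.6), including those at elt-3, rpl-11.2, nhr-14, col-166, col-167 and his-24. It carries 13.7% of protein-coding genes (odds ratio 2.41, 2-sided Fisher's exact p = 6.69e-09) and 17.7% of the sequence (exact binomial p = 9.39e-05). Of the other pooled regions 19.8% lay on X, fewer than of the peaks (Fisher's exact p = 0.00257). In each replicate taken alone 62 of the 253 strongest regions (24.5%) lay on X, more than the share of genes (Fisher's exact p = 5.25e-06) but not detectably more than the share of the replicate's other regions (19.6% in replicate 1, Fisher's exact p = 0.0559; 20.3% in replicate 2, Fisher's exact p = 0.0985). These comparisons with other regions were chosen after the data were seen. Without the 6 peaks within 20 kb of elt-3 the share was 25.9%, and among the 126 peaks of larger signal it was 22.2%.

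Near tRNA genes, a known place of background in worm ChIP-seq, 2 of 253 summits lay within 200 bp (0.791%, 95% exact binomial interval 0.0959 to 2.83), against 0.323% at random (permutation p = 0.198). In the strongest regions of replicate 2 alone there were 4 (1.58%, permutation p = 0.00805). Peaks with and without WGATAR had median signal values of 49.7 and 51.3, a difference of -0.043 on the log2 scale that did not pass (permutation p = 0.375, n = 112 and 141), and in the strongest regions of replicate 1 alone it was 0.069 (permutation p = 0.156).

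The elt-3 locus held many regions. The 40 kb around the gene, which spans 13934874 to 13941216 on the plus strand of chromosome X, held 29 pooled regions covering 7161 bp (7.25 regions per 10 kb), more than 99.8% of windows of that size, whose median was 12 (percentile between 94.6 and 100 by the Poisson interval of the count, and from 84.9 in replicate 1). Without the 9 regions within the gene, the 20 others lay at the 98.3 percentile of windows treated alike, at 87.2 in replicate 1 and 99.2 in replicate 2. Of the 29 regions, 6 were optimal peaks, 4 of them in the same intron of elt-3 with signal values of 46.6, 57.8, 140.2 and 57.0 from the 5′ end on. Transgenic lines made in unc-119 mutants carry unc-119 as a rescue marker, and the 40 kb around unc-119 on chromosome III held 12 regions covering 3000 bp and no optimal peak (percentile 47.2, between 10.9 and 96.2 by the Poisson interval of the count). Transgene and endogenous copies cannot be separated in these lists.

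**Figure D3:**
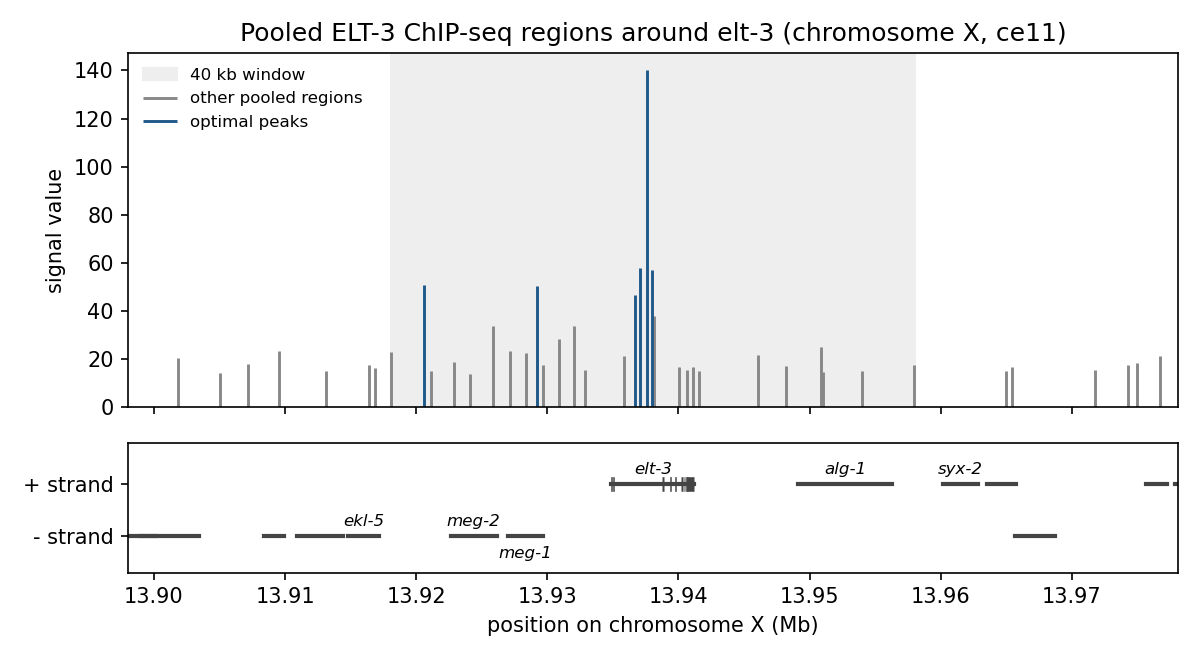
Signal value (y axis, the authors' units) and summit position (x axis, Mb on chromosome X, ce11) of pooled regions around elt-3, with optimal peaks in blue, other regions in grey, the 40 kb window shaded, and genes and elt-3 exons drawn below by strand. The peak at 140.2 lies in an intron of elt-3, with 3 further optimal peaks in the gene and 2 upstream of it.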

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

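This count was chosen after the motif result for the optimal set was seen. Outside the optimal set, the pooled regions ranked 254 to 1000 held WGATAR within 50 bp of the summit in 292 of 747 cases (39.1%, 95% exact binomial interval 35.6 to 42.7), above the 19.4% in their own flanks (odds ratio 2.66, Fisher's exact p = 1.03e-22). The share was 27.4% among the next 1000 regions and 20.3% among the last 14000. In ranks 254 to 1000 it was 40.1% outside promoters and 36.9% in promoters. No biological explanation was tested.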

How the results depend on the processing

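The splits by place and by GATA site and the correlation over pooled regions were chosen after seeing the data. Of 97 planned comparisons over 18 results, 82 kept their direction and side of the threshold, or moved within their interval, as did 10 of 20 added ones. The promoter share (33.99% to 63.6%) passed under every alternative run, as did the share on X (21.7% to 32.0%) against that of genes, but not against each replicate's other regions (Fisher's exact p = 0.0559 and 0.0985). The WGATAR share passed under every setting fixed in advance, and in promoters alone it was 27.4% (Fisher's exact p = 0.330). Ribosomal protein genes passed Fisher's exact test under all of those (adjusted p from 1.75e-27 to 9.13e-08), but at peaks outside promoters their odds ratio was 0, and at peaks with WGATAR 8.87 (adjusted p = 0.267). The number of lists past the threshold was 3 with every gene within 2000 bp counted, 2 of them through neighbouring genes that shared 1 or 2 peaks, and 0 with peaks outside promoters or peaks with WGATAR alone.

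Odds ratios of lists that did not pass fell to 0 for collagens among the peaks of larger signal, and for histones outside promoters and with WGATAR; without 1 replicate that of histones ranged from 0 to 5.09, and with every gene counted it was 7.15 (Fisher's exact test, adjusted p = 0.0234). The tRNA share was 0% of the 126 peaks of larger signal and ranged from 0.395% to 1.58% without 1 replicate. The log2 signal difference by motif was 0.069 for the peaks of larger signal, 0.041 for TGATAA, and -0.0098 to 0.069 without 1 replicate. More frequent words numbered 53 for the peaks of larger signal, 72 in promoters and 77 outside them, sets with fewer peaks. Matches to replicate 2 rose to 100% with any overlap, and among the peaks of larger signal 81.0% and 86.5% were in the strongest regions of replicates 1 and 2. The Spearman correlation of the replicates' signal values was 0.0459 for the peaks of larger signal and 0.289 over all matched regions. The percentile of unc-119 was 4.46 in replicate 1 within 10 kb, from 2 regions. Apart from the smaller sets of peaks, the cause was not tested. No paired analysis was possible because there was 1 group. Read depth was unknown, so what it limits was not estimated.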

Other observations

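The tests of ranks under the optimal set, of product names and of base arrangements, the comparison of ribosomal protein gene peaks with other promoter peaks, the count of regions around elt-3 without the gene, the split of GATA sites by place with its further checks, and the comparisons of chromosome X with other regions of the lists were chosen after the data were seen. Below the optimal set, in ranks 254 to 2000, 2 lists passed Fisher's exact test against all genes, osmotic response and epidermal antimicrobial peptides. These regions were nearest to 4 of 10 osmotic response genes (odds ratio 12.5, Fisher's exact p = 0.00107, adjusted p = 0.0236), namely the glycerol-3-phosphate dehydrogenase genes gpdh-1 and gpdh-2 and the genes osm-7 and osm-11. They were also nearest to 5 of 20 epidermal antimicrobial peptide genes, cnc-5, cnc-8, cnc-10, nlp-24 and nlp-33 (odds ratio 6.28, Fisher's exact p = 0.0027, adjusted p = 0.0297), and to 17 of 170 cuticle collagen genes (odds ratio 2.10, Fisher's exact p = 0.0072, adjusted p = 0.0528), which did not pass. Other epidermal lists did not pass either, with 6 of 52 genes of molting and the non-collagen cuticle (odds ratio 2.45, Fisher's exact p = 0.0466, adjusted p = 0.171), 3 of 26 patched-related genes (adjusted p = 0.391), 2 of 15 regulators (adjusted p = 0.426), 2 of 18 junction and attachment genes (adjusted p = 0.507) and 1 of 59 hedgehog-related genes (adjusted p = 0.725 by Fisher's exact test). Against genes near a pooled region, ribosomal protein genes passed as well (7 of 27, odds ratio 3.77, Fisher's exact p = 0.00627, adjusted p = 0.046). No difference from the optimal set was tested. Markers of intestine and germline had 0 of 20 and 0 of 22, and those of body muscle, pharynx and neurons 1 each (unc-87, tnt-4 and mec-7). These counts show no depletion, since 5.07% of other genes were nearest to such a region (Fisher's exact p = 0.622 for intestine and 0.626 for germline). The lists of body muscle, pharynx and neurons did not pass either. With the optimal set included, ranks 1 to 1000 gave 3 lists against all genes, ribosomal proteins, antimicrobial peptides (4 of 21, adjusted p = 0.0218) and cuticle collagens (13 of 174, odds ratio 2.70, Fisher's exact test, adjusted p = 0.0215). Against genes near a pooled region 1 list passed there, ribosomal proteins, and collagens did not (Fisher's exact test, adjusted p = 0.0695). In all, 10 combinations of rank range and background were tried, without adjustment across them. For ranks 254 to 1000 against all genes 0 of 22 lists passed Fisher's exact test after adjustment and 6 did unadjusted, and against genes near a pooled region 1 passed, ribosomal proteins (6 of 27, odds ratio 7.54, adjusted p = 0.00826). For ranks 254 to 500 the numbers were 0 and 2 with either background, and among the 1000 regions that end at rank 2000 no list passed with either background by Fisher's exact test (2 and 1 unadjusted).

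Among 481 words of gene product names, 7 passed after adjustment. Genes named as ribosomal were bound in 12 of 196 cases (odds ratio 9.09, Fisher's exact p = 3.72e-08, adjusted p = 1.79e-05). Genes named as serpentine, a term of the chemoreceptor families, were bound in 0 of 1074 cases, against 0.809% of other genes (Fisher's exact p = 0.000413, adjusted p = 0.0284). Of 12 arrangements of the 4 core bases of WGATAR, the GATA order had the largest excess at summits over flanks (20.8 percentage points), followed by WTAAGR (14.8) and WAGATR (13.4), which both occur in AGATAAG when extended.

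The ribosomal protein gene peaks held WGATAR less often than the other peaks (15.4% against 45.8%, Fisher's exact p = 0.0427), which argues against binding through GATA sites at most of them. All 13 lay in promoters, and the other promoter peaks held WGATAR in 29.03% of cases, a share not told apart from theirs (Fisher's exact p = 0.507). The low share was thus not shown to be particular to these genes. The 13 are the peaks nearest to a ribosomal protein gene, while 22 peaks lay within 2000 bp of one. The other peaks, and possibly the other promoter peaks, therefore include some near ribosomal protein genes, which limits both comparisons. The list passed in each replicate alone (Fisher's exact test, larger adjusted p = 9.13e-08), which argues against 1 library as the source. Pull-down at active promoters without a GATA site remains a candidate explanation, which the comparison with flanks cannot decide. The share of 15.4% was not above the 19.2% of their flanks (Fisher's exact p = 1). That compares only 2 of 13 summits with 5 of 26 flank windows. The exact binomial interval of the share, from 1.92% to 45.4%, holds both the share of the flanks and that of the other promoter peaks. Promoter activity was not measured, the control experiment was not analysed here, and no biological explanation other than GATA sites was tested.

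Of the other pooled regions 19.8% lay on chromosome X, fewer than the 27.7% of peaks (Fisher's exact p = 0.00257). An excess in the region lists as a whole may therefore account for part of the excess over genes but, for the optimal set taken whole, not all. The X share was 22.2% among the 126 peaks of larger signal, and 25.9% without the peaks near elt-3. Neither share was tested against the other pooled regions. The excess over genes was present in each replicate alone (Fisher's exact p = 5.25e-06 in both). The other regions of each replicate also stood above the 13.7% of genes, at 19.6% and 20.3%. The comparison with genes therefore cannot tell whether a further excess of the peaks came from 1 library. The further excess over a replicate's own other regions did not pass in replicate 1 (24.5% against 19.6%, Fisher's exact p = 0.0559) or in replicate 2 (24.5% against 20.3%, Fisher's exact p = 0.0985). Whether the excess on X came from peaks without a GATA site stayed open, since 25% of peaks with WGATAR and 29.8% of those without lay on X, shares that were not told apart (Fisher's exact p = 0.480). No biological explanation was tested.

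Whether extra copies of the elt-3 region in the strain may contribute to its peaks stayed open. The surrounding 40 kb lay at the 99.8 percentile of windows by number of pooled regions, but that count of 29 includes the 9 regions in the gene. The 20 others lay at the 98.3 percentile, with a counting interval from 74.2, and at 87.2 in replicate 1. The window of unc-119, the rescue marker of such strains, lay at the 47.2 percentile with a wide interval too. The number of copies was not measured, and no biological explanation was tested.

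The difference in GATA sites between peaks outside and in promoters (56.5% against 27.4%, Fisher's exact p = 6.08e-06) might reflect 2 kinds of peak, a hypothesis that the same split cannot test. It held without the 13 peaks nearest to ribosomal protein genes (Fisher's exact p = 3.55e-05) but not in replicate 1 alone (Fisher's exact p = 0.0604). Peaks within 2000 bp of such genes but nearer to another gene were not removed. In the pooled regions ranked 254 to 1000, which took no part in finding it, the shares were 40.1% and 36.9% and did not differ detectably (Fisher's exact p = 0.423). Over all other pooled regions, most of them weak, they were 20.9% and 23.03% (Fisher's exact p = 0.000184). The ratio of the replicates' signal did not detectably separate peaks with a site from those without (difference of median log2 ratios -0.01, permutation p = 0.886).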
